A study of Homo sapiens with 18 samples.

How the data were processed

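RNA sequencing libraries were made from BEAS-2B human bronchial epithelial cells, 18 in all: 6 control, 6 exposed to house dust mite (HDM) for 24 h, and 6 given HDM with an anti-IL-6 receptor antibody for 24 h. Per the labels the libraries were poly(A)-selected and strand-specific (dUTP method). The submitters' notes list fastp 0.19.7, HISAT2 2.0.5, featureCounts 1.5.0-p3, DESeq2 1.20.0 and the GRCh38 genome without giving their roles. The step that made the FPKM values, the annotation release and the strand used in counting are not stated. The deposited table holds FPKM values, 1 column per library, for 61710 features, with a gene length in base pairs (an other unit, not an expression value, per the file headers).

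FPKM multiplied by the listed length fell on whole multiples of 1 step per library for 100% of values, within a tolerance of 0.01, so reads per gene could be recovered. The library size that the deposited scaling implies lay between 0.977 and 1.03 times the sum of those reads. Reads in genes ranged from 1.54e+07 to 1.71e+07 (mean 1.62e+07 ± 4.85e+05, SD, n = 18). The limit that 0 reads allow was taken as 3 reads, which is 0.175 to 0.197 FPKM at 1 kb. Intervals and floors cover counting error only. DESeq2 and edgeR were not run. Count tools were planned only for a file of raw counts, and this file gives FPKM. Limma-voom on the recovered reads was added as an alternative after the data were seen.

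Genes with a mean FPKM of at least 0.5 over the 18 libraries were tested (14294). log2(FPKM + 0.5) values went into 1 limma fit of 3 group means with an intensity trend (limma 3.58.1, R 4.3.3), and p-values were adjusted by Benjamini and Hochberg over all genes, with a threshold of 0.05. The pseudocount shrinks the log2 differences of genes near 0.5 FPKM. The 3 comparisons were HDM against control, HDM with antibody against HDM, and HDM with antibody against control. Genes changed at least 2-fold were counted as well. 18 fixed genes of IL-6 signalling, mucus, PI3K and mTOR and epithelial cytokines were tested by exact two-sided permutation of the difference in mean log2 value, adjusted over the 18 genes. 34 gene lists were fixed, covering the groups reported below together with markers of leukocytes, fibroblasts and ciliated cells and signs of RNA quality. Lists with at least 5 measured members (31) were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists, and again with an estimated correlation, which gave each list past the threshold its highest adjusted p among the alternatives, except the type 2 list for antibody against HDM (0.055, and 0.161 with the mixed test of fry). With an estimated correlation 2 lists passed in each comparison.

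The comparisons, tests, lists, naming rule and the alternatives not said to be added were set before the data were examined. The genes named are the 18 fixed genes, per comparison the 10 largest rises and the 10 largest falls, and up to 4 members with the smallest p of each list described. The rises and falls were taken among protein-coding genes past the threshold with a mean of at least 1 FPKM in a group and no overlap between groups. Genes outside this rule are said to have been chosen after their values were seen. The biotype column of the file calls 61533 of 61710 features protein coding and could not serve the rule, so gene types came from GENCODE release 29, matched by gene identifier for 58356 features, of which 58312 share the chromosome and 42424 the start and end. 123 symbols sit on more than 1 feature, and the feature with the highest mean was used. TMEM16A and RIGI are not in the file under these names.

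The 11 alternatives set at that time, besides leaving out each library in turn, were a replicate block, pseudocounts of 0.1 and 1, no filter and a mean of at least 1 FPKM, median of ratios scaling (which gave all 18 libraries nearly the same factor and so tests nothing), quantile normalization, a fit of only the 2 groups, no intensity trend, array quality weights, and protein-coding genes only. For lists, an estimated correlation and fry were run, and for fixed genes limma. 4 alternatives were added after the data were seen: limma-voom, total-read scaling, the first within-group principal component as a covariate, and leaving out HDM replicate 6 and antibody replicate 3, the exposed libraries nearest the controls on the first principal component (23.1% of variance). Replicate numbers are not said to mark shared cultures. Correlations of within-group deviations between libraries of the same number ran from -0.144 to 0.0933 with 0 of 18 above 0.1, so no pairing was used, and no 2 libraries were identical. The same number gave the highest correlation in 3 of 6 cases for control and HDM, 1 of 6 for control and antibody, and 0 of 6 for HDM and antibody.

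On simulated data, changes of 1.3, 1.5 and 2-fold were recovered in 55.6%, 62.1% and 91.4% of genes for HDM against control and in 65.5%, 71.4% and 88.1% for antibody against HDM, with 5 of 139 and 10 of 157 calls false. For HDM with antibody against control the shares were 57.4%, 77.8% and 84.8%, with 5 of 149 false. Each comparison had a single draw, with genes independent of each other, a spread smoothed over genes and changes in few genes. The draws held no variation shared by genes between libraries of a group. The shares are therefore not error rates of the real comparisons. Tables were made with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures with matplotlib 3.10.9. Reads shared by near-identical genes (KRT6A with KRT6B and KRT6C, SAA1 with SAA2, SERPINB3 with SERPINB4, mitochondrial genes with their nuclear copies) cannot be separated in a gene-level table.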

Results

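The series measured gene expression in BEAS-2B cells, an immortalised human bronchial epithelial line, in 18 RNA sequencing libraries. 6 libraries came from untreated control cells, 6 from cells exposed to house dust mite (HDM) for 24 h, and 6 from cells given HDM with an anti-IL-6 receptor antibody for 24 h. The labels give no time for the control cells and no dose, and no group received the antibody alone or an isotype control. Reads in genes, recovered from the deposited FPKM values, numbered 1.54e+07 to 1.71e+07 per library, with group means of 1.65e+07 ± 5.21e+05 in control, 1.59e+07 ± 4.51e+05 in HDM and 1.63e+07 ± 3.62e+05 in HDM with antibody (SD, n = 6 in each). A count of 0 reads allows up to 0.175 to 0.197 FPKM for a gene of 1 kb, depending on the library, for counting error only. All values after ± are SD for FPKM and SE for log2 differences, each over 6 libraries per group. The p-values measure only the spread between these samples, which can be technical.

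The comparison of HDM with control addresses what mite exposure changes in bronchial epithelial cells, and with it the genes of IL-6 signalling and mucus. CYP1A1, a cytochrome P450 that oxidises aromatic hydrocarbons (ENSG00000140465_15, GRCh38 chromosome 15, 74719542 to 74725536), rose from 0.933 ± 0.236 FPKM in control to 12.1 ± 1.55 in HDM (SD, n = 6). PI3, which encodes the elastase inhibitor elafin, rose from 4.47 ± 1.37 to 19.9 ± 3.57 FPKM. S100A7, S100A8 and S100A9, genes of calcium-binding proteins of stressed epithelium, rose: S100A7 from 7.54 ± 1.12 to 27.0 ± 4.70 FPKM, S100A8 from 15.5 ± 2.51 to 50.4 ± 8.09, and S100A9 from 281 ± 34.9 to 692 ± 85.9. KRT6A, a keratin of wounded and thickened epithelium, rose from 28.4 ± 1.72 to 92.0 ± 15.2 FPKM, and SAA1, an acute phase protein, from 250 ± 42.1 to 717 ± 90.4. ANKRD1, CCN1 and CCN2, genes that respond to cell tension and growth factors, fell: CCN1 (ENSG00000142871_18, chromosome 1, 85580761 to 85584589) from 71.9 ± 5.21 to 23.0 ± 1.02 FPKM.

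On the log2 scale the rise was 3.15 ± 0.10 for CYP1A1 (limma adjusted p = 3.8e-13), 2.06 ± 0.14 for PI3 (9.5e-09), 1.77 ± 0.12 for S100A7 (8.8e-09), 1.66 ± 0.08 for KRT6A (3.4e-11) and 1.52 ± 0.12 for SAA1 (2.7e-08). DNER, a membrane ligand of Notch, rose by 1.33 ± 0.07. PDZK1IP1, a small membrane protein, and PRR15L rose by 1.26 ± 0.15 and 1.24 ± 0.12. The largest fall under the naming rule was that of ANKRD1, at -2.29 ± 0.17 (adjusted p = 2.4e-08). CCN1 and CCN2 each fell, with -1.62 ± 0.06 and -1.62 ± 0.07. The monocyte chemoattractant CCL2 fell from 5.67 ± 1.11 to 1.39 ± 0.33 FPKM (-1.70 ± 0.13), and the transcription factor KLF2 fell with -1.86 ± 0.15. The TNF family ligands TNFSF18 and LTB fell with -1.86 ± 0.11 and -1.80 ± 0.16, TNFSF18 from 385 reads over the 6 control libraries to 8 over the HDM libraries. LCE1F, a cornified envelope gene, had -1.69 ± 0.18, and the interferon-stimulated genes IFIT1 and IFI44L had -1.60 ± 0.10 and -1.57 ± 0.11. In each of these 20 genes every HDM library lay beyond every control library. In the other genes given here as risen or fallen with mite, all 6 HDM libraries lay on that side of the control mean, except 5 of 6 for POLE, SFN, TP63 and COX6C and 4 of 6 for SDHD.

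Of 14294 genes tested with limma, 4564 passed an adjusted p of 0.05 (31.9%), 2154 of them higher and 2410 lower in HDM. With total-read scaling the balance turned, to 2474 higher and 2084 lower. The changes were mostly small, with a median size of 0.27 (log2), and 118 genes changed at least 2-fold, 56 up and 62 down. The groups did not overlap in 2033 genes (14.2%), where chance gives 0.216%. Without the 2 exposed libraries nearest the controls, HDM replicate 6 and antibody replicate 3, 5292 genes passed. The count at 2-fold and its balance depend on the log scale and the genes tested. It was 205 with a pseudocount of 0.1 (106 up, 99 down), 64 with a pseudocount of 1 (30 and 34), 64 among protein-coding genes (16 and 48) and 225 with limma-voom (121 and 104).

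**Figure D1:**
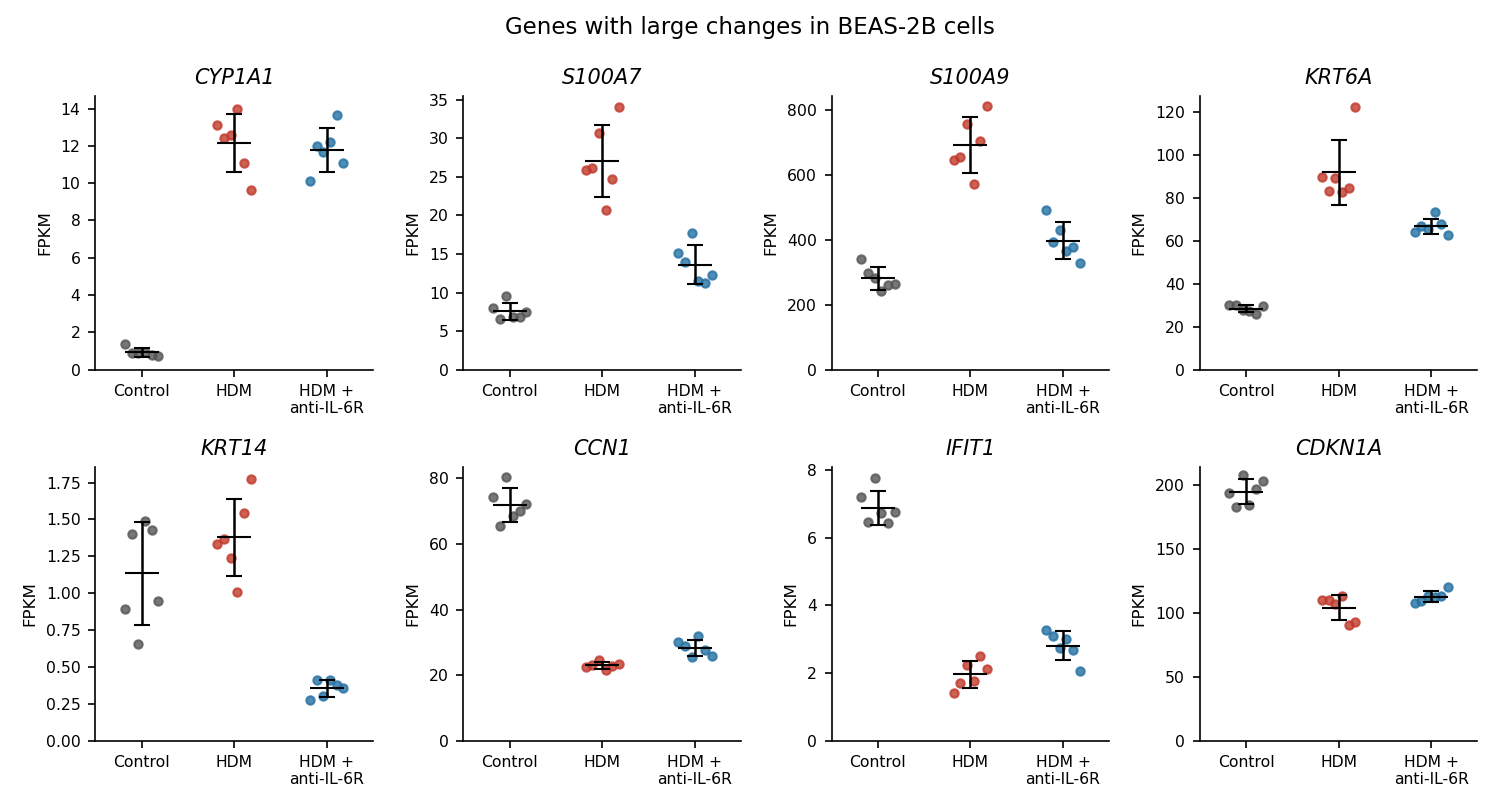
FPKM (vertical axes, from 0) of 8 genes in each library, by group: points are libraries and bars are the mean ± SD of 6. CYP1A1 lies between 9.66 and 14 in the HDM libraries against a control mean of 0.933, S100A7 and S100A9 are high in HDM and lower with the antibody, and CCN1, IFIT1 and CDKN1A are lower in both exposed groups.

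IL6 itself fell after mite exposure, from 3.44 ± 0.522 FPKM in control to 1.14 ± 0.341 in HDM (699 and 228 reads over the 6 libraries; ENSG00000136244_12, chromosome 7, 22725884 to 22732002). CXCL8, a neutrophil chemokine (ENSG00000169429_11, chromosome 4, 73740541 to 73743716), fell from 19.9 ± 2.43 to 8.40 ± 2.14. IL6R, the receptor subunit that binds IL-6 (ENSG00000160712_13, chromosome 1, 154405193 to 154469450), rose from 7.58 ± 0.437 to 11.6 ± 1.32, while IL6ST, the shared signalling subunit, fell from 29.3 ± 1.62 to 23.0 ± 1.73. SOCS3, a feedback inhibitor induced by STAT3 (ENSG00000184557_4, chromosome 17, 78356778 to 78360077), fell from 11.6 ± 1.94 to 6.56 ± 0.934. The membrane mucin MUC1 (ENSG00000185499_17, chromosome 1, 155185824 to 155192916) rose from 15.7 ± 1.01 to 25.2 ± 3.27.

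By exact two-sided permutation tests with adjustment over the 18 fixed genes, 9 passed, 4 higher and 5 lower. The log2 differences were -1.28 for IL6, -1.22 for CXCL8, 0.58 for IL6R, -0.35 for IL6ST, -0.77 for SOCS3, 0.66 for MUC1, 0.16 for the kinase MTOR and -0.27 for the translation repressor EIF4EBP1. Each had an exact two-sided permutation p = 0.00216, the smallest these arrangements can give (adjusted 0.00487), with all 6 HDM libraries beyond all controls. PIK3R1, the regulatory subunit of PI3K, rose by 0.26, with 5 of 6 HDM libraries above every control (exact p = 0.00433, adjusted 0.00866). STAT3 had 18.7 ± 0.772 and 18.4 ± 0.505 FPKM (exact adjusted p = 0.518), and exact adjusted p was 0.745 for AKT1, 0.618 for RPS6KB1 and 0.87 for PIK3CA. The gel-forming mucin MUC5AC (ENSG00000215182_8, chromosome 11, 1157953 to 1201138) gave 81, 42 and 64 reads over the control, HDM and antibody libraries, with 4 to 23 reads in a control library and 2 to 10 in an HDM library (exact adjusted p = 0.129 for HDM against control). MUC5B gave 43, 38 and 36 reads, the goblet cell regulator SPDEF 48, 26 and 33, and the epithelial cytokines TSLP and IL33 gave 93, 103 and 54 and 11, 3 and 0 reads. The 0 reads of IL33 with antibody allow up to 0.00936 FPKM over the group. Exact adjusted p for HDM against control was 0.759, 0.351, 0.612 and 0.216 for these 4 genes.

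**Figure D2:**
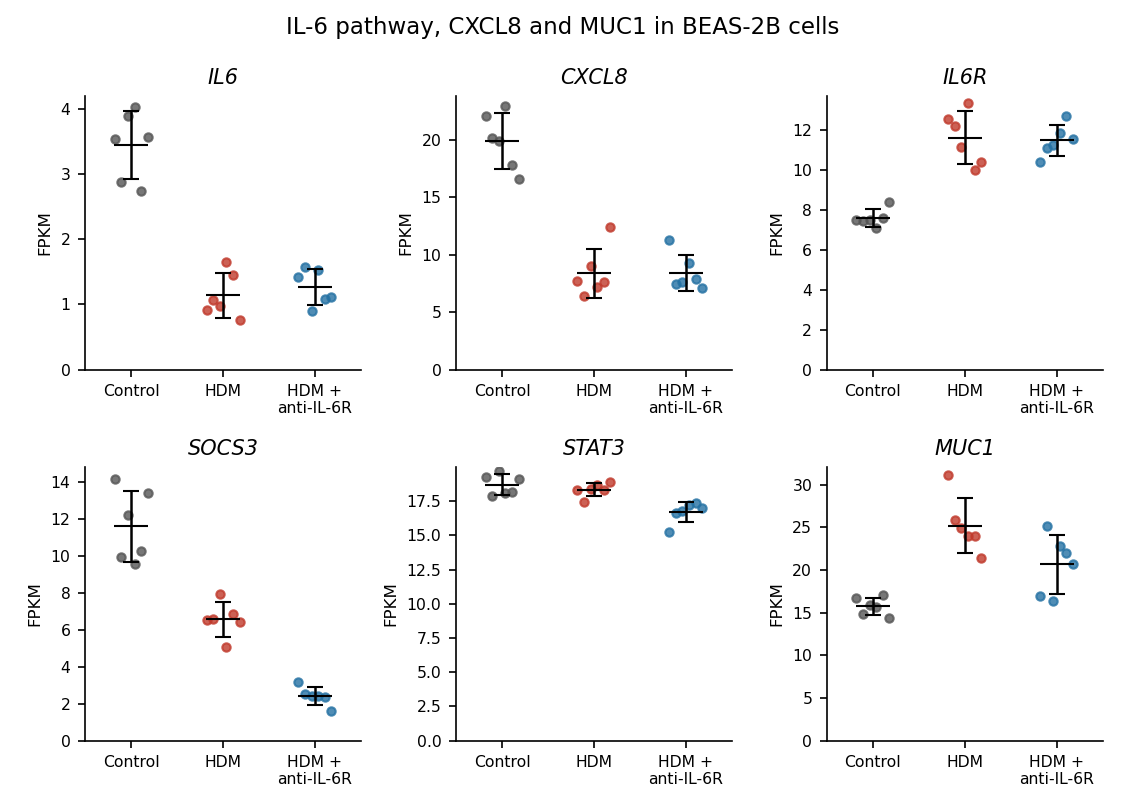
FPKM (vertical axes, from 0) of IL6, CXCL8, IL6R, SOCS3, STAT3 and MUC1 in each library, by group: points are libraries and bars are the mean ± SD of 6. IL6 and CXCL8 are lower and IL6R higher in both exposed groups, and SOCS3 steps down from 11.6 to 6.56 to 2.41.

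Among 22 measured STAT3 target and acute phase genes, 7 rose and 9 fell (7 and 9 adjusted over the list alone). The list as a whole did not pass (camera adjusted p = 0.974), with a median of -0.07, a mean of 0.05 and a test direction upward. The risers included the secreted defence proteins LCN2 (0.73 ± 0.05), SAA2 (0.92 ± 0.07) and SERPINA1 (0.58 ± 0.05). Of 13 IL-6 family genes 2 rose and 4 fell (3 and 6 adjusted over the list alone; camera adjusted p = 0.247). IL27RA rose beside IL6R (0.35 ± 0.08), and the shedding protease ADAM10 and the cytokine LIF, with -0.23 ± 0.04 and -0.56 ± 0.11, fell beside IL6 and IL6ST. IL27RA and LIF were chosen after their values were seen. Of 36 components of the PI3K, AKT and mTOR pathway 6 rose and 10 fell (8 and 10 adjusted over the list alone; camera adjusted p = 0.189), among the fallers the lipid phosphatase INPP5D (-0.98 ± 0.08) and the insulin receptor substrates IRS1 (-0.50 ± 0.06) and IRS2 (-0.46 ± 0.05). 4 of 16 mucins were expressed enough to test: MUC1, MUC4 (0.69 ± 0.14) and MUC20 (0.37 ± 0.08) rose, and MUC16 had 0.15 ± 0.10. Of 7 measured goblet cell and mucin processing genes the glycosyltransferase GALNT12 rose (0.55 ± 0.06) and MARCKS (-0.43 ± 0.04) and AGR2 (-0.45 ± 0.09), which act in granule release and mucin folding, fell, 1 and 3 adjusted over the list alone (camera adjusted p = 0.504).

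The lists that fell with mite exposure were led by interferon-stimulated genes: 27 of 30 fell and 1 rose (28 and 1 adjusted over the list alone), with a median of -0.79. The antiviral genes MX1 (-1.09 ± 0.07), IFI44 (-1.49 ± 0.10) and IFIT1 fell, while the chemokine CXCL11, chosen after its value was seen, rose by 0.78 ± 0.18. The camera adjusted p was 1.94e-23, and adjusted p = 0.0441 with an estimated correlation. Of 26 targets of the tumour suppressor p53, 23 fell (24 adjusted over the list alone), among them the cell cycle inhibitor CDKN1A, from 195 ± 9.97 to 104 ± 9.87 FPKM (-0.91 ± 0.05), the stress cytokine GDF15 (-1.09 ± 0.08) and the kinase PLK2 (-0.85 ± 0.05). The p53 list had a camera adjusted p of 1.11e-16, with adjusted p = 0.0175 with an estimated correlation. Of 30 immediate early and ERK feedback genes 22 fell (26 adjusted over the list alone; camera adjusted p = 3.43e-13, adjusted p = 0.0755 with an estimated correlation), as in FOS (-1.3 ± 0.10), DUSP5 (-1.10 ± 0.08) and JUNB (-0.62 ± 0.06). Of 33 DNA replication genes 26 fell and POLE rose, POLE chosen after its value was seen (28 and 1 adjusted over the list alone; camera adjusted p = 2.96e-10, adjusted p = 0.0755 with an estimated correlation). The helicase subunits MCM6 and MCM7 had -0.39 ± 0.05 and -0.30 ± 0.04. POLE rose by 0.22 ± 0.07, and its adjusted p of 0.0218 became 0.056 without HDM replicate 1 and 0.0517 without HDM replicate 4.

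Of 28 matrix and mesenchymal genes 16 fell and 5 rose (18 and 5 adjusted over the list alone; camera adjusted p = 5.81e-06, adjusted p = 0.112 with an estimated correlation). CCN1, CCN2, the matrix protein THBS1 (-1.15 ± 0.07) and SPARC (-0.55 ± 0.04) fell. Fibroblast markers moved with them, 2 of 4 falling, with a median of -0.44 (camera p = 0.00634, not adjusted, and 0.0359 with an estimated correlation). With 4 measured members that list was below the minimum of 5 set for testing, and its faller COL1A1 is also in the matrix list. TNC, a matrix protein of wound repair (1.17 ± 0.10), LOX, LOXL2 and ITGA5, chosen after their values were seen, were among the 5 matrix genes that rose. LOXL2 (0.15 ± 0.05) lost its call without control replicates 3, 4 and 5 or HDM replicate 1 (0.0509 to 0.0635). Of 31 genes of amino acid supply and stress driven by ATF4, 16 fell and SLC7A5, an amino acid transporter chosen after its value was seen, rose (18 and 1 adjusted over the list alone; camera adjusted p = 2.25e-06, adjusted p = 0.0755 with an estimated correlation). ATF3 had -1.34 ± 0.09 and PYCR1, an enzyme of proline synthesis, -0.58 ± 0.06. Of 21 antigen presentation genes 12 fell and NLRC5, chosen after its value was seen, rose (12 and 1 adjusted over the list alone; camera adjusted p = 0.00297, adjusted p = 0.191 with an estimated correlation), with -0.48 ± 0.07 for the immunoproteasome subunit PSMB9.

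NF-kB dependent cytokine and feedback genes went both ways: 12 of 28 fell and 7 rose (12 and 8 adjusted over the list alone). CCL2, CXCL1 (-1.35 ± 0.11) and CSF1 (-0.48 ± 0.04) were among the fallers, and the survival gene BIRC3 rose by 0.70 ± 0.08. The list's camera adjusted p was 0.0383, and adjusted p = 0.415 with an estimated correlation. It was 0.0509 to 0.0589 without control replicate 1 or 3 or HDM replicate 2, 4 or 5, and 0.0505 to 0.0975 with a replicate block, quantile normalization, only the 2 groups, protein-coding genes only or a within-group principal component as covariate. Over the alternatives with camera it ran from 6.13e-05 to 0.415, and fry, which tests the list against no change, gave 2.32e-04 and, for change in either direction, 1.97e-17.

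Genes of squamous and basal keratinocytes rose: 15 of 24, with 5 falling (15 and 5 adjusted over the list alone; camera adjusted p = 8.95e-05, adjusted p = 0.0755 with an estimated correlation). The fallers, chosen after their values were seen, were the simple epithelial keratins KRT8 and KRT18, the protease inhibitor CSTA, SFN and the basal cell factor TP63. SFN (-0.17 ± 0.06) lost its call without control replicates 1, 3, 5 and 6 or HDM replicates 1, 2, 4 and 5 (0.0638 to 0.0878), and TP63 (-0.13 ± 0.05) without control replicates 1, 4 and 6 or HDM replicates 1, 2, 4 and 5 (0.0678 to 0.103). Cholesterol synthesis genes rose in 13 of 24 cases (16 adjusted over the list alone; camera adjusted p = 5.17e-06, adjusted p = 0.275 with an estimated correlation), as in LSS (0.50 ± 0.05), MVK (0.48 ± 0.06) and DHCR7 (0.41 ± 0.05). Of 16 fatty acid synthesis genes 9 rose and SCD5 fell with -0.37 ± 0.05 (9 and 1 adjusted over the list alone; camera adjusted p = 0.000916, adjusted p = 0.191 with an estimated correlation), FASN rising from 116 to 172 FPKM (0.57 ± 0.07). Of 31 mitosis genes 10 rose and 1 fell (11 and 1 adjusted over the list alone; camera adjusted p = 0.000962, adjusted p = 0.415 with an estimated correlation). The mitotic kinase PLK1 rose by 0.48 ± 0.05, and the faller was CDK1, chosen after its value was seen, whose call was lost without control replicates 1, 2, 4 and 5 or HDM replicates 1, 2 and 4 (0.0546 to 0.0896). Of 5 measured type 2 response genes the serpins SERPINB3 (0.79 ± 0.15), SERPINB4 (1.07 ± 0.21) and SERPINB2 rose (3 adjusted over the list alone). That list had a camera adjusted p of 0.0383, with adjusted p = 0.289 with an estimated correlation, and 0.0509 to 0.0632 without control replicate 3 or 5 or HDM replicate 6. SERPINB2 rose by 0.43 ± 0.15 and its adjusted p of 0.038 was 0.0526 to 0.0736 without any 1 of the 6 control libraries or HDM replicate 1, 5 or 6.

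Markers of other cell types gave these values. Of 23 leukocyte genes 2 were expressed enough to test, and LAPTM5 (0.39 ± 0.10, from 1.49 to 2.10 FPKM) and CSF1R (0.43 ± 0.12) rose. Of 4 measured fibroblast genes FBLN2 (-1.11 ± 0.07) and COL1A1 (-0.52 ± 0.07) fell, and both are expressed in this line without exposure. Of 6 measured ciliated cell genes TUBB4B, MCIDAS and CCNO rose (3 adjusted over the list alone; camera adjusted p = 0.154). As signs of RNA quality, the share of reads from the mitochondrial genome was 4.20 ± 0.211% in control, 5.10 ± 0.355% in HDM and 5.25 ± 0.517% with antibody (SD, n = 6), and 11 of 15 mitochondrial genes rose and MT-RNR1, chosen after its value was seen, fell (12 and 1 adjusted over the list alone; camera adjusted p = 0.000717, adjusted p = 0.415 with an estimated correlation, 0.117 with quantile normalization). MT-ND5 rose by 0.57 ± 0.10. Of 47 ribosomal protein genes 19 fell (35 adjusted over the list alone; camera adjusted p = 3.02e-07, adjusted p = 0.458 with an estimated correlation), as in RPLP1 (-0.18 ± 0.05). Of 37 nuclear respiratory chain genes UQCRFS1, COX5B, NDUFS3, COX6C and SDHD fell (1 adjusted over the list alone; camera adjusted p = 0.0367, adjusted p = 0.59 with an estimated correlation). That list had 0.0544 to 0.139 without control replicate 1, 2 or 5 or HDM replicate 1, 2 or 4. NDUFS3 lost its call without control replicate 1, 2, 3 or 5 or HDM replicate 1 or 4 (0.0586 to 0.0854), and COX6C without control replicate 1, 3 or 5 or HDM replicate 1, 2, 4 or 5 (0.0601 to 0.0974). SDHD, chosen after its value was seen, lost its call in 11 such fits, without control replicate 1, 2, 4 or 6, HDM replicates 1 to 4 or antibody replicate 2, 5 or 6 (0.0506 to 0.105). CCNO lost its call without control replicates 2 to 6, HDM replicate 1, 2, 3 or 5 or antibody replicate 2, 4 or 5 (0.0508 to 0.0974).

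**Figure D3:**
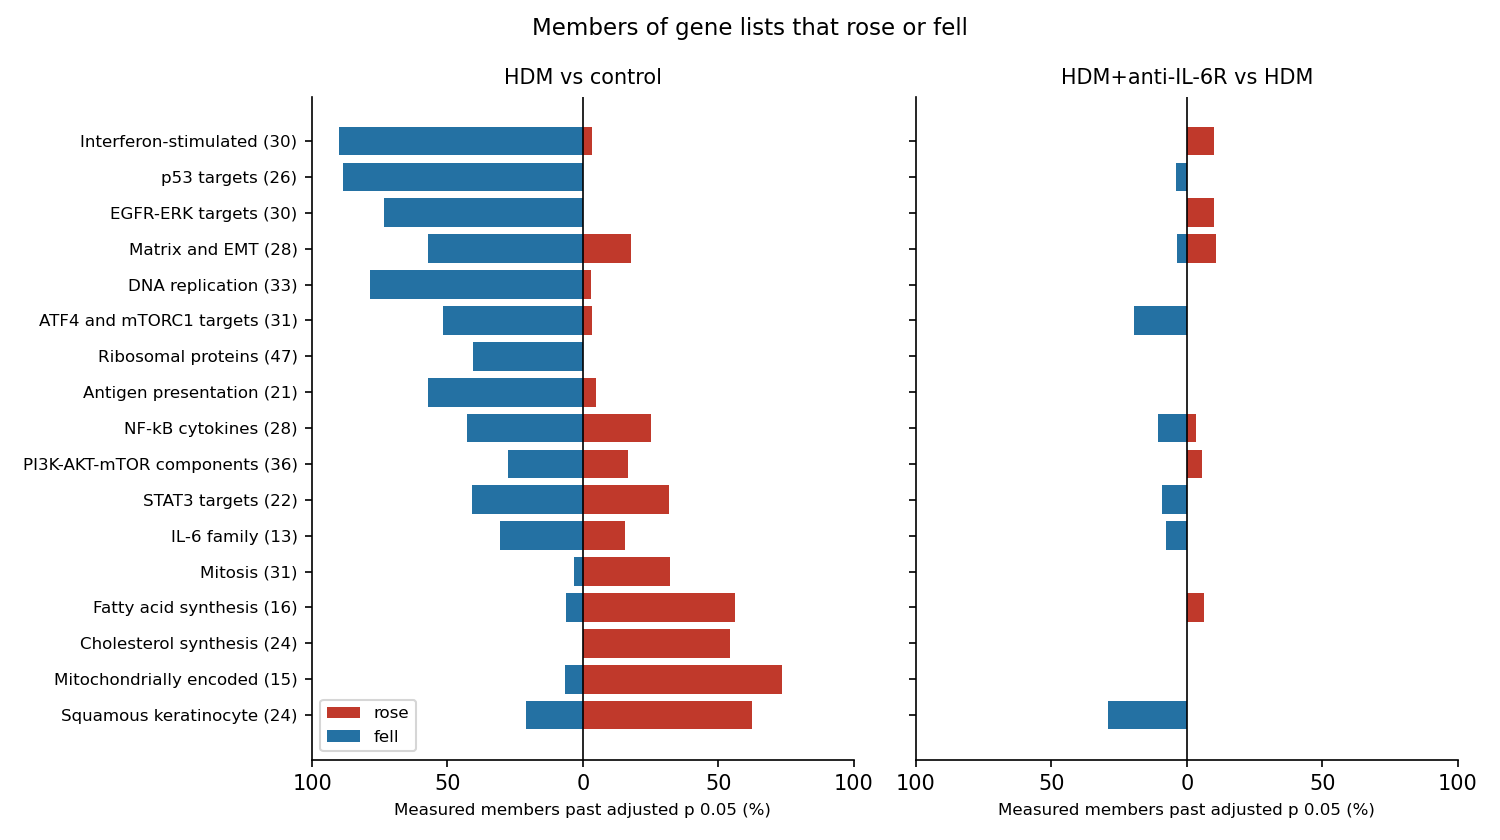
Share of each list's measured members that passed an adjusted p of 0.05 (horizontal axis, percent; fallers to the left, risers to the right) for 17 gene lists, with HDM against control and HDM with antibody against HDM in separate panels. Interferon and p53 target genes fell in most members after mite exposure (27 of 30 and 23 of 26), and the squamous list had 15 risers of 24 with mite and 7 fallers with the antibody.

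The comparison of HDM with antibody against HDM alone addresses what adding the anti-IL-6 receptor antibody changes in mite-exposed cells. SOCS3, the STAT3 feedback gene, fell from 6.56 ± 0.934 to 2.41 ± 0.485 FPKM (SD, n = 6), by 1.29 on the log2 scale. KRT14, a basal keratin (ENSG00000186847_6, chromosome 17, 41582279 to 41586895), fell from 1.38 ± 0.263 to 0.355 ± 0.0581 FPKM, from 300 to 79 reads over the 6 libraries. These S100 genes fell from their level with mite alone: S100A7 from 27.0 ± 4.70 to 13.6 ± 2.51, S100A8 from 50.4 ± 8.09 to 27.2 ± 6.39 and S100A9 from 692 ± 85.9 to 398 ± 57.2 FPKM. TFCP2L1, an epithelial transcription factor (ENSG00000115112_8, chromosome 2, 121216587 to 121285202), rose from 4.32 ± 0.333 to 7 ± 0.550, and GAS1, a growth arrest protein, from 19.8 ± 2.46 to 29.4 ± 4.30.

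Of 14294 genes, 212 passed limma's adjusted p of 0.05 (1.48%), 119 higher and 93 lower, and 1606 had an unadjusted p under 0.05. SOCS3 (-1.29 ± 0.12, adjusted p = 5.0e-05) and KRT14 (-1.13 ± 0.13, 2.3e-04) changed at least 2-fold. This count of 2 was 9 with a pseudocount of 0.1, 1 at a mean FPKM of at least 1, and 6 without HDM replicate 2 or 4. The groups did not overlap in 235 genes (1.64%), against 0.216% by chance. Beside S100A7 (-0.96 ± 0.12), S100A8 (-0.89 ± 0.14) and S100A9 (-0.80 ± 0.10), the largest falls were those of SERPINB3 (-0.66 ± 0.15), the chromatin protein HMGA2 (-0.48 ± 0.08), KRT6A (-0.45 ± 0.08), the cytokine IL1A (-0.43 ± 0.07) and ERICH2 (-0.75 ± 0.17; 59 and 23 reads). Rises were 0.70 ± 0.11 for the kinase MAPK4, 0.69 ± 0.11 for the protease inhibitor SERPINA5, 0.67 ± 0.11 for the adrenergic receptor ADRA1B, 0.64 ± 0.07 for TFCP2L1 (adjusted p = 1.7e-04), 0.58 ± 0.12 for PRR15L and 0.56 ± 0.09 for GAS1. C1QL1 (0.54 ± 0.09), CYP26A1, which degrades retinoic acid (0.51 ± 0.10), the potassium channel subunit KCNS3 (0.50 ± 0.11) and METTL7A (0.49 ± 0.11) also rose. In each of these 20 genes every antibody library lay beyond every HDM library, and in every other gene given here as risen or fallen with the antibody all 6 lay on that side of the HDM mean.

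Some of these calls lie near the threshold. KCNS3 was lost without HDM replicate 1 or 2 or antibody replicate 2, 3 or 5 (0.0528 to 0.0655). METTL7A was lost without HDM replicate 1, 2 or 6 or antibody replicate 2, 4 or 6 (0.0545 to 0.07), and SERPINB3 without HDM replicate 3, 4 or 5 or antibody replicate 2 or 3 (0.0502 to 0.0655). ERICH2 was lost without HDM replicate 2, 3, 5 or 6 or antibody replicate 1, 2, 4 or 5 (0.0502 to 0.0693), and PRR15L, with adjusted p of 5.63e-04 to 0.0614 over the alternatives, without both HDM replicate 6 and antibody replicate 3 (0.0614). The count of 212 was 127 without antibody replicate 2, 139 without antibody replicate 4, 134 in a fit of only the 2 groups, 135 with a replicate block, 114 with no filter on low values, and 174 without HDM replicate 6 and antibody replicate 3. Higher counts were 228 without HDM replicate 6, 257 with limma-voom and 385 with the first within-group principal component as a covariate.

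Of the fixed genes, SOCS3 and STAT3 passed the exact two-sided permutation test, each with p = 0.00216, the smallest possible (adjusted 0.0195), and with all 6 antibody libraries below all HDM libraries. STAT3 (ENSG00000168610_16, chromosome 17, 42313324 to 42388540) fell by 0.13, from 18.4 ± 0.505 to 16.7 ± 0.751 FPKM; limma's adjusted p over all genes was 0.0676, and 0.0475 to 0.164 over the alternatives. MUC1 had 25.2 ± 3.27 FPKM in HDM and 20.6 ± 3.44 with antibody, a difference of -0.29 with 3 of 6 antibody libraries below every HDM library (exact p = 0.039, adjusted 0.175). TSLP had a difference of -0.26 (exact p = 0.013, adjusted 0.0779). IL6 had 1.14 ± 0.341 and 1.27 ± 0.278 FPKM, with an exact adjusted p of 0.744, and IL6R, IL6ST and CXCL8 each had 0.911. MTOR (ENSG00000198793_13, chromosome 1, 11106535 to 11262551) had 13 ± 0.353 and 12.5 ± 0.920 FPKM, a difference of -0.05 (exact adjusted p = 0.633), and exact adjusted p was 0.911 for PIK3R1, 0.833 for EIF4EBP1, 0.552 for AKT1, 0.744 for RPS6KB1 and 0.584 for PIK3CA. MUC5AC, MUC5B, SPDEF and IL33 had exact adjusted p of 0.552, 0.911, 0.833 and 0.744.

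Among the lists, 7 of 24 squamous genes fell with the antibody (12 fell and 2 rose adjusted over the list alone; camera adjusted p = 5.25e-10, adjusted p = 0.0107 with an estimated correlation). They included KRT14, KRT6A, TP63 (-0.34 ± 0.05) and the 3 S100 genes above. Of 31 ATF4 driven amino acid and stress genes 6 fell (13 adjusted over the list alone; camera adjusted p = 2.01e-13, adjusted p = 0.0107 with an estimated correlation), including the mTORC1 inhibitor SESN2 (-0.30 ± 0.05) and the pseudokinase TRIB3 (-0.29 ± 0.05). STAT3 targets fell as a list (camera adjusted p = 8.31e-04, adjusted p = 0.171 with an estimated correlation), with SOCS3 and the protease inhibitor SERPINA1 (-0.40 ± 0.05) called of 22, and 6 adjusted over the list alone. The type 2 list fell with SERPINB3 called of 5 (3 adjusted over the list alone; camera adjusted p = 6.44e-05, adjusted p = 0.055 with an estimated correlation and 0.161 with the mixed test of fry).

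Interferon-stimulated genes rose with the antibody (camera adjusted p = 2.40e-10, adjusted p = 0.153 with an estimated correlation): IFIT2 (0.36 ± 0.07), IFI44 (0.47 ± 0.10) and IFIT1 (0.43 ± 0.10) of 30 over all genes, and 11 adjusted over the list alone. IFI44 was lost without HDM replicate 3 or 4 or antibody replicate 1, 2 or 4 (0.0501 to 0.0652), and IFIT1 without HDM replicate 1, 2 or 4 or antibody replicates 1 to 5 (0.0614 to 0.0907). Of 28 matrix genes SPARC (0.28 ± 0.04), CCN1 (0.29 ± 0.06) and FN1 (0.29 ± 0.07) rose and TNC (-0.52 ± 0.10) fell (9 and 1 adjusted over the list alone; camera adjusted p = 1.55e-06, adjusted p = 0.105 with an estimated correlation). Markers of fibroblasts moved with them, and FBLN1 rose (0.26 ± 0.05). COL1A1, which is in both lists, had 0.24, FBLN2 0.14 and S100A4 0.26 (2 of 4 adjusted over the list alone; median 0.25, camera p = 1.49e-04, not adjusted, and 0.00593 with an estimated correlation). The fibroblast list, with 4 measured members, was below the minimum of 5 set for testing. Of the 2 leukocyte genes LAPTM5 had -0.18 and CSF1R 0.12. None of 6 ciliated cell genes passed limma or limma-voom, with 1 higher and 1 lower at an unadjusted p under 0.05 (camera adjusted p = 0.828). FN1 was lost without HDM replicate 2, 3 or 4 or antibody replicates 1 to 5 (0.0552 to 0.1). Of the other fixed lists, OSMR, the oncostatin M receptor (-0.28 ± 0.05), was the IL-6 family member that fell, and FOXO1 (0.34 ± 0.06) and PIK3R3 (0.29 ± 0.06) rose among the 36 PI3K pathway genes (2 adjusted over the list alone; camera adjusted p = 0.109, and 0.0405 without HDM replicate 6). PIK3R3 had 0.0667 without HDM replicate 6 and antibody replicate 3. Of 28 NF-kB genes NFKBIA rose (0.30 ± 0.06) and IL1A, IL1B and ICAM1 fell (2 and 3 adjusted over the list alone; camera adjusted p = 0.356). IL1B was lost without HDM replicate 2, 3 or 5 or antibody replicate 1, 2, 3, 4 or 6 (0.0571 to 0.0784), and ICAM1 without HDM replicates 1 to 4 or antibody replicate 1, 3, 4, 5 or 6 (0.0559 to 0.0866).

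Cholesterol synthesis genes were higher with the antibody as a list (camera adjusted p = 1.64e-05, adjusted p = 0.279 with an estimated correlation). None of 24 passed alone with limma, 6 were higher at an unadjusted p under 0.05, 2 rose adjusted over the list alone and 2 with limma-voom. Unfolded protein response genes were lower as a list (camera adjusted p = 6.44e-05, adjusted p = 0.305 with an estimated correlation), with none of 24 past limma's threshold, 4 lower at an unadjusted p under 0.05, 1 adjusted over the list alone and 1 with limma-voom. Fatty acid synthesis genes were higher (camera adjusted p = 2.22e-04, adjusted p = 0.153 with an estimated correlation) with SCD5 called of 16 and 5 higher and 1 lower adjusted over the list alone. SCD5 rose by 0.20 ± 0.05, and its adjusted p of 0.042 was 0.0518 to 0.0946 without control replicate 2 or 3, HDM replicates 1 to 4 or antibody replicates 1 to 5.

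The remaining lists that passed were higher with the antibody by small amounts, with medians of 0.04 to 0.13. Several also differed between exposed libraries of the same group, along the first within-group principal component. Camera adjusted p along it was 1.63e-12 for ribosomal protein, 1.80e-08 for respiratory chain, 8.39e-04 for heat shock and 0.00479 for DNA replication genes. It was 0.00137 for the interferon genes above, and 0.752 and 0.649 for histone and antigen presentation genes. The component was computed from these same values, so these p-values describe which lists it holds and are not independent tests. Library variation was not separated from an antibody effect for any of these lists. DNA replication genes had a camera adjusted p of 0.00499 (adjusted p = 0.368 with an estimated correlation; 0.0612 without antibody replicate 3), with none of 33 past limma's threshold, 6 higher at an unadjusted p under 0.05, 1 adjusted over the list alone and none with limma-voom. Antigen presentation genes had 0.0154 (adjusted p = 0.279 with an estimated correlation; 0.0533 without HDM replicate 4 and 0.0522 without antibody replicate 2), with none of 21 past the threshold of limma, over the list alone or limma-voom, and 3 higher at an unadjusted p under 0.05. Histone genes had 0.0128 (adjusted p = 0.0986 with an estimated correlation), with none of 18 past limma or limma-voom, 4 higher at an unadjusted p under 0.05 and 2 adjusted over the list alone. Their mRNAs lack a poly(A) tail and the libraries were poly(A)-selected, so this list was set as a sign of library quality. Respiratory chain genes had 0.00371 (adjusted p = 0.637 with an estimated correlation; 0.056 to 0.139 without HDM replicate 1 or 4 or antibody replicate 1 or 3) and ribosomal protein genes 0.0258 (adjusted p = 0.861 with an estimated correlation; 0.109 to 0.601 without HDM replicate 1, 2 or 4 or antibody replicate 1 or 3). In the former none of 37 and in the latter none of 47 passed limma, over the list alone or limma-voom, with 2 and 0 higher at an unadjusted p under 0.05. Of 20 heat shock and metallothionein genes the chaperone DNAJB1 rose by 0.17 ± 0.03 (3 adjusted over the list alone; camera adjusted p = 0.0386, adjusted p = 0.558 with an estimated correlation; 0.0821 to 0.216 without HDM replicate 1, 2 or 4 or antibody replicate 1 or 3). Mitochondrially encoded genes did not pass as a list, but had a camera adjusted p of 0.00615 without antibody replicate 3.

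The comparison of HDM with antibody against control shows how far cells with both treatments lay from untreated cells. CYP1A1 was at 11.8 ± 1.19 FPKM, 3.11 ± 0.10 above control on the log2 scale (adjusted p = 4.7e-13), and PI3 at 21.1 ± 2.04 (2.15 ± 0.14). PTGES, which makes prostaglandin E2, rose from 163 ± 9.66 to 385 ± 21.8 FPKM (1.24 ± 0.07), and the calcium-binding S100P from 25.1 ± 5.27 to 62.1 ± 9.17 (1.3 ± 0.12). SOCS3 stood at -2.06 ± 0.12 (adjusted p = 1.3e-09), and the antimicrobial peptide DEFB1 fell from 157 to 23 reads over the 6 libraries (-2.06 ± 0.34). PRR15L, TFCP2L1, DNER, SAA1, ADRA1B and ABLIM3 made up the rest of the 10 largest rises, at 1.3 to 1.81, and ANKRD1, TNFSF18, LTB, KLF2, ATF3, CCL2, LCE1F and FOSB the rest of the falls, at -1.80 to -1.41.

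Of 14294 genes 4254 passed (29.8%), 1995 higher and 2259 lower (2262 and 1923 with total-read scaling), and 105 changed at least 2-fold, 59 up and 46 down. That count was 180 with a pseudocount of 0.1 (111 up, 69 down), 57 with a pseudocount of 1 (32 and 25) and 209 with limma-voom (125 and 84). Among protein-coding genes the balance turned, with 24 up and 38 down of 62. The groups did not overlap in 2052 genes (14.4%; chance 0.216%), and 4941 genes passed without HDM replicate 6 and antibody replicate 3. Of the 18 fixed genes 9 passed the exact permutation test: IL6R, PIK3R1 and MUC1 (0.37, adjusted 0.0216, 4 of 6 libraries above every control) were higher, and IL6, IL6ST, SOCS3, STAT3 (-0.16), EIF4EBP1 and CXCL8 lower. Interferon genes fell in 26 of 30 cases (camera adjusted p = 2.53e-18, adjusted p = 0.0689 with an estimated correlation), p53 targets in 23 of 26 (3.08e-16, adjusted p = 0.0128 with an estimated correlation) and ATF4 driven genes in 21 of 31 (2.50e-13, adjusted p = 0.0128 with an estimated correlation). Cholesterol genes rose in 19 of 24 cases (5.44e-10, adjusted p = 0.125 with an estimated correlation) and fatty acid genes in 11 of 16 (3.76e-06, adjusted p = 0.0951 with an estimated correlation). Adjusted over the list alone, 27, 25 and 24 fell and 20 and 11 rose in these lists. The squamous list did not pass here (11 rose and 6 fell of 24, 11 and 6 adjusted over the list alone; camera adjusted p = 0.0875), with KRT6A still 1.22 ± 0.08 above control.

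Of the genes called in both the mite and the antibody comparison, 77 moved in opposite directions and 59 in the same one. S100A7, S100A8, S100A9, KRT6A, SERPINB3, HMGA2 and TNC were among the 31 that rose with mite and fell with antibody, and CCN1, SPARC, IFIT1 and IFI44 among the 46 that did the reverse. TFCP2L1, ADRA1B and GAS1 were among 33 genes that rose in both, and SOCS3 and IL1A among 26 that fell in both. Independent lists of these sizes and directions would give 34.1 and 33.6 genes. Because both comparisons use the HDM libraries with opposite sign, unchanged groups give a negative correlation of the effects across genes (-0.503 in simulation, -0.342 observed), and genes are not independent replicates. In 100 such simulations the covariance was -0.0125 on average (-0.0162 observed), and 0.08 opposite genes were called on average and 8 at most (77 observed). The simulated groups held no real effects for the shared libraries to tilt, so the 77 cannot be judged against them. In 20 ways of splitting the HDM libraries between the comparisons, opposite genes outnumbered same-direction genes in 11, with means of 21.9 and 19.7. In all 20 splits the squamous list's median was at least 0.24 with mite and at most -0.12 with antibody, and the interferon list's at most -0.66 and at least 0.09, while the ATF4 list's was at most -0.17 and at most -0.11. The 20 splits all use the same control and antibody libraries and are not independent. The counts of 77 and 59 were 51 and 37 without antibody replicate 2, and same-direction genes numbered 36 to 39 without HDM replicate 2, 3 or 4 or antibody replicate 4 or 5.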

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

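The tests of library scaling and of the within-group gradient were chosen only after the results they measure were seen, as was the final reading of the test of shared HDM libraries. The split medians of the squamous, interferon and ATF4 lists were not among the tests set beforehand. The tests of YAP targets, of the CYP1A1 share and of GC content or gene length had bounds set before they were run. Those bounds came after the patterns they address had been seen. The comparison with other splits of the libraries was set beforehand.

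Among 596 groups of 6 values, 27 had 1 library whose gap to the nearest of the others took a share of the group's range above Dixon's 95% critical value, where chance gives about 29.8 (1 in 20). HDM replicate 6 gave 10 of the 27. In that library KRT6A was at 122 FPKM (82.7 to 89.8 in the others), SERPINB4 at 14.3 (5.01 to 8.08), SERPINB2 at 1.87 (at most 1.05), HMGA2 at 3.19 (2.28 to 2.52), IL1A at 28.6 (22.3 to 24.5), ID1 at 102 (81.4 to 87.7), PMAIP1 at 36.3 (30.8 to 32.2), KRT8 at 185 (149 to 162) and KRT18 at 238 (193 to 208), and INPP5D was low at 4.48 (5.90 to 6.55). In HDM replicate 2, CYP2S1 stood at 1.47 FPKM (0.656 to 0.865) and DEFB1 at 1.74 (0 to 0.508), and in HDM replicate 4 SPDEF stood at 0.463 (0 to 0.155) and SPARC at 35.5 (37.0 to 37.7). MUC5B was at 0.0396 in HDM replicate 1 (0.0129 to 0.0212) and TIMP2 at 17.8 in HDM replicate 3 (18.9 to 19.5).

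Of the control libraries, replicate 1 had CYP1A1 at 1.39 FPKM (0.725 to 0.927 in the others), PLAU at 73.6 (65.4 to 68.0) and TIPARP at 4.60 (5.37 to 5.6). Control replicate 2 had MT1M at 0.817 (0 to 0.252), control replicate 3 had DSG2 at 35.0 (40.1 to 43.0), and control replicate 4 had IL6ST at 32.4 (27.9 to 29.4) and CTSL at 9.78 (11.3 to 11.8). With the antibody, replicate 6 had IFI44 at 3.55 (4.71 to 5.03) and JUNB at 42.6 (51.8 to 55.1), replicate 1 had STAT3 at 15.3 (16.7 to 17.4) and replicate 4 had NFE2L2 at 13.5 (14.5 to 15).

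HDM replicate 6 and antibody replicate 3 stood apart from their groups along a gradient shared within groups (14.3% of within-group variance), with higher ribosomal protein, respiratory chain, mitosis, heat shock, interferon, NRF2 and DNA replication genes (list medians of -0.09 to -0.03 per SD of the gradient, counted toward the other exposed libraries) and lower mitochondrially encoded and unfolded protein response genes (0.12 and 0.05). A smaller share of the mite effect in these libraries (weaker exposure or admixed control RNA) may contribute. CYP1A1 was at 9.66 FPKM in HDM replicate 6 against 12.4 to 14 in HDM replicates 1 to 4, so that 27.9% of its rise was missing in FPKM and 12.7% on the log2 scale. The log2 deviations of HDM replicate 6 and antibody replicate 3 followed the other exposed group's difference from control, with slopes of -0.21 and -0.27. These libraries were picked as the exposed ones nearest the controls on the first principal component, which separates control from exposed libraries. Negative slopes therefore followed from that choice and are no support for a smaller share. HDM replicate 5 and antibody replicate 1, the next nearest on that component, had slopes of -0.15 and -0.21 as well. Their CYP1A1 of 11.1 and 10.1 FPKM was also below the reference libraries of their groups. Against a smaller share, CYP1A1 in antibody replicate 3 was 11.7, within 11.1 to 13.7 of antibody replicates 2, 4, 5 and 6. Among the far-out genes of HDM replicate 6 given above, KRT6A, SERPINB4, SERPINB2, HMGA2 and INPP5D lay further from control than in the other HDM libraries. IL1A, PMAIP1, KRT8 and KRT18 lay nearer to control, and ID1 was not called with mite. A smaller share alone does not account for genes that lay further from control. On the log2 scale rising genes missed 26.3% and 37.6% of their change in HDM replicate 6 and antibody replicate 3, where falling genes missed 13.9% and 14.4%. The share and another difference between libraries cannot be told apart. GC content also stays open, since the Spearman correlation across genes of the gradient with GC content was 0.224, between the bounds set beforehand. With gene length the correlation was 0.0559, under the lower bound, which argues against length as the source. The design names no biological difference within groups, and no biological explanation was tested.

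After mite exposure 12 of 28 NF-kB cytokine genes, 22 of 30 immediate early genes and 27 of 30 interferon genes fell, with medians over all measured members of -0.18, -0.50 and -0.79; the cytokine list went both ways, with 7 risers and an adjusted p = 0.415 with an estimated correlation. Scaling between libraries as the cause is argued against, since the 61 fallers, whose median of -0.68 is low by selection, kept at least 92.7% of it under quantile normalization, total-read scaling and the protein-coding rescaling, and the medians over all members were -0.16 to -0.18, -0.47 to -0.49 and -0.78 to -0.82 there. These scalings differ little from the deposited one: the median over all genes tested was -0.0041, 0.024 and -0.0096, against 0.0020 before. They speak only to scaling of this kind, and a change in total RNA per cell was not tested. Denser or less spread cells in the exposed dishes could contribute, but cell density was not measured. Targets of the tension-sensitive factor YAP were examined instead, and no link from them to these genes was tested, so the test does not decide it. CCN1, CCN2 and ANKRD1 had been seen to fall, which made a fall of other YAP targets likely. Those other targets were lower as a set (camera p = 3.33e-10, and 8.11e-04 with an estimated correlation). Of 18 measured 13 fell, as in AMOTL2 (-0.97), NUAK2 (-0.90) and AJUBA (-0.68), and DOCK5 rose by 0.25; these genes were chosen after their values were seen. An effect of mite itself and a different time or density of the control cells, for which the labels give no time, stay open, and no value here separates them.

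Genes called in both comparisons moved in opposite directions more often than in the same one (77 and 59). The within-group gradient stays open: as a covariate it averages 0 in every group and so left each difference as it was, and the 162 opposite and 90 same-direction genes of that fit (a ratio of 1.8) could not have shown it to be the cause or not. With the HDM libraries split between the comparisons, the covariance over genes called in HDM with antibody against control was below 0 in 5 of 20 splits, which by the bound set beforehand would speak for the shared HDM libraries as the cause. That bound was wrong, because genes called in that comparison are those whose effects add up, which pulls the covariance upward, and over all genes it was below 0 in 15 of 20; simulated groups with no change gave at most 8 opposite genes, but they hold no real effects for the shared libraries to tilt, so shared libraries and an opposing antibody effect cannot be told apart for the genes as a whole. The split medians of the squamous and interferon lists kept their opposite signs in all 20 splits, while the ATF4 list was lower in both comparisons in all 20. Within a split the comparisons share no HDM library. All splits use the same control and antibody libraries, and these lists were not set beforehand for this use. The 20 splits are therefore not independent support for an opposing antibody effect.

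Against 99 other splits of the same libraries, chance can be excluded for the number of genes called in each comparison. For HDM against control the 2-group fit called 4390 genes and 116 at 2-fold, with 521 and 15 as the highest of the other splits and 1 of 100 as large, the real one. For antibody against HDM it called 134 and 4, with 5 and 1 as the highest others (1 of 100), and for HDM with antibody against control 4303 and 105, with 496 and 15 (1 of 100). For the number of lists past the threshold, antibody against HDM gave 15, with 1 of 100 splits as large, the real one. The highest other split gave 14 lists, so the margin is narrow and chance is not firmly excluded. These other splits called at most 5 genes but passed up to 14 lists, so many lists can pass at the preset correlation without the real grouping. Chance could not be excluded for HDM against control (15 lists, highest other 16, 5 of 100 as large) or for HDM with antibody against control (13 lists, highest other 14, 10 of 100).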

How the results depend on the processing

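Limma-voom, total-read scaling, the gradient covariate and leaving out 2 exposed libraries were chosen only after the results were seen. No result past the threshold reversed its direction under any alternative run, and the cause of the changes below was not tested unless stated. The count of genes called for HDM against control ran from 3851 to 5151 and for HDM with antibody against control from 3560 to 4582 when 1 library was left out. Total-read scaling turned the balance in these 2 comparisons to 2474 higher and 2084 lower and to 2262 and 1923. For antibody against HDM it was 135 with the replicate block, 114 with no filter (more genes tested), 134 in a fit of only the 2 groups (fewer samples), 385 with the gradient covariate, which leaves every difference as it was and lowers the residual spread, and 127 to 228 without 1 library (127 without antibody replicate 2 and 139 without antibody replicate 4). Counts at 2-fold for HDM against control were 205 with a pseudocount of 0.1 and 64 with 1, which shrinks fold changes by construction, 64 among protein-coding genes only, 225 with limma-voom, and 98 to 129 without 1 library. For antibody against HDM they were 9 with a pseudocount of 0.1, 1 at a mean FPKM of at least 1 (fewer genes tested), 4 in a fit of only the 2 groups, 4 with limma-voom, 4 with the gradient covariate, and 2 to 6 without 1 library: 4 without control replicate 4, HDM replicate 1 or antibody replicate 5, and 6 without HDM replicate 2 or 4. For HDM with antibody against control they were 180, 57, 62 and 209 with pseudocounts of 0.1 and 1, protein-coding genes only and limma-voom, and 91 to 124 without 1 library. Lists past the threshold fell to 2 in each comparison with an estimated correlation. They numbered 30 and 29 with fry's mixed test in the comparisons with control and 9 with its directional test for antibody against HDM, since fry asks another question, and 14 to 17, 11 to 16 and 13 to 14 without 1 library. Genes opposite in both effects numbered 39 with no filter, 45 in a fit of only the 2 groups, 162 with the gradient covariate and 51 to 97 without 1 library (51 without antibody replicate 2). Same-direction genes numbered 30, 39, 90 and 36 to 62, with 36 without HDM replicate 4 or antibody replicate 4, 37 without HDM replicate 2 or antibody replicate 2 or 5, and 39 without HDM replicate 3. With limma in place of the exact test 1 fixed gene passed for antibody against HDM. Among named genes, 6273 of the checks under the alternatives set beforehand kept their side of the threshold, 132 lost it and 69 gained it. When 1 library was left out, 10282 kept it, 286 lost it and 70 gained it. The planned count tools were not run, as the file holds FPKM values. Depth limits IL33, with 0 to 4 reads per library. MUC5AC, MUC5B, SPDEF and TSLP gave at most 23, 14, 18 and 27 reads in a library, and depth was not tested as the reason for their p-values.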

Other observations

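The tests of YAP targets, aryl hydrocarbon receptor targets and BMP targets were set down before those lists were measured, but after the genes that prompted them had been seen. The verdict rule for the aryl hydrocarbon receptor was changed after its result was seen.

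Several fixed gene lists moved in parts with mite exposure. Of 33 glycolysis and hypoxia genes 7 rose and 4 fell (7 and 4 adjusted over the list alone; camera adjusted p = 0.684): the glycolytic regulator PFKFB4 (0.51 ± 0.10) and the lipase inhibitor ANGPTL4 (0.90 ± 0.17) rose, and the oxygen sensor EGLN3 (-0.48 ± 0.09), BNIP3L, PFKL and GAPDH fell, the last 3 chosen after their values were seen. Of 29 junction and epithelial identity genes 8 rose and 7 fell (8 and 8 adjusted over the list alone; camera adjusted p = 0.808, upward, with a median of 0.02 and a mean of -4.45e-04), with DSG2, a desmosomal cadherin, up by 0.42 ± 0.05 and CTNNB1, which encodes beta-catenin, at -0.48 ± 0.05. Of 18 proteases and inhibitors 7 rose and 3 fell (7 and 3 adjusted over the list alone; camera adjusted p = 0.154): the metalloprotease ADAM8 rose by 0.67 ± 0.08, and the plasminogen activator PLAU (-0.27 ± 0.06), TIMP2 and TIMP3 fell. TIMP2 and TIMP3 were chosen after their values were seen, and TIMP2 lost its call without control replicate 1 or 4 or HDM replicate 3 (0.0503 to 0.0613). Of 33 cell death genes 7 rose and 11 fell (7 and 13 adjusted over the list alone; camera adjusted p = 0.222), with the pro-death gene BMF up by 0.98 ± 0.07 and PMAIP1, also pro-death, at -0.62 ± 0.05. Of 14 receptors and adaptors that sense mite products 6 rose and 3 fell (6 and 4 adjusted over the list alone; camera adjusted p = 0.411, upward with a median of 0.11): TLR2 rose by 0.40 ± 0.08, and the protease-activated receptors F2R (-0.75 ± 0.06) and F2RL1 (-0.50 ± 0.05) and TLR3, chosen after its value was seen, fell.

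Of 24 unfolded protein response genes 8 fell and the ubiquitin ligase SYVN1 rose by 0.42 ± 0.08 (8 and 1 adjusted over the list alone; camera adjusted p = 0.132, and 0.0404 to 0.0421 without control replicate 3 or 4), with the chaperone HSP90B1 at -0.29 ± 0.04. Of 27 antioxidant genes of NRF2, GCLM (0.35 ± 0.07) and PRDX1 rose and 6 fell (2 and 6 adjusted over the list alone; camera adjusted p = 0.241), among them NFE2L2, which encodes NRF2 itself (-0.33 ± 0.05). PRDX1, chosen after its value was seen, had 0.0504 to 0.0729 without control replicate 3, 4 or 6 or HDM replicate 5 or 6. Of 34 autophagy and lysosome genes 7 fell, as in MAP1LC3B (-0.41 ± 0.05), and NPC1, CTSL, ATG16L1, LAMP1 and LAMP2, chosen after their values were seen, rose (7 and 5 adjusted over the list alone; camera adjusted p = 0.581, downward with a median of 0.01 and a mean of -0.03). LAMP2 had 0.0518 without control replicate 3. Of 18 histone genes H1-2 (-0.41 ± 0.09), H2BC11, H3C10 and H2AC6 fell (4 adjusted over the list alone; camera adjusted p = 0.189). The histone list was set as a sign of library quality, since these mRNAs lack a poly(A) tail. Of 20 heat shock and metallothionein genes the metal-binding MT2A (0.92 ± 0.12) and MT1E (0.68 ± 0.11) rose with MT1F, MT1M and HSPB1, and the zinc exporter SLC30A1 (-0.52 ± 0.06), HSPA4L, DNAJA1 and HSPD1 fell (5 and 4 adjusted over the list alone; camera adjusted p = 0.684). MT1F, MT1M, HSPB1, DNAJA1 and HSPD1 were chosen after their values were seen, HSPD1 was lower in 5 of 6 HDM libraries, and MT1M had 0.0559 to 0.068 without control replicate 1, 4, 5 or 6 or HDM replicate 2, 5 or 6.

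A first hypothesis is that the aryl hydrocarbon receptor, which drives CYP1A1, was activated by mite exposure. Other targets were tested together: CYP1B1 (0.51) and TIPARP (0.50) rose, NQO1, whose fall had been seen beforehand, had -0.21, and CYP2S1 had -0.16, with a camera p of 0.263 over the 4 measured of 9 listed (0.391 with an estimated correlation). The bound set down beforehand would have spoken against the hypothesis at this p, but that bound was wrong: CYP1B1 and TIPARP rose past the threshold and NQO1 fell, and a test over 4 members that go both ways decides nothing, so the hypothesis stays open. The 4 genes were chosen for the hypothesis after CYP1A1 was seen.

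A further hypothesis is that BMP and SMAD signalling may be higher with the antibody, since ID3 (35.4 FPKM in HDM and 48.5 with antibody; 0.45 ± 0.05, adjusted p = 1.9e-04) and BMP2 (2.26 and 3.36 FPKM; 0.49 ± 0.08, 0.0031) rose. Both were chosen after their values were seen. Other BMP targets were higher together, with a camera p of 1.71e-05 over the 5 measured of 10 listed (5.31e-04 with an estimated correlation) and a median of 0.33. Of the 5, ID1 rose alone past the threshold over all genes (0.34, adjusted p = 0.0107), so the pattern fits the hypothesis on few genes and was found and tested on the same data.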
